A study of Mus musculus with 3 samples.

How the data were processed

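Single cells from mouse gallbladder were profiled on a droplet platform with 3′ gene expression libraries, sequenced as paired-end reads. Per the labels, each of the 3 groups was 1 library from 10 pooled gallbladders of male mice, digested with trypsin. The deposited matrix holds raw UMI counts made with Cell Ranger 6.1.1 per the file headers, with GRCm38 (mm10) as genome build per the labels. The authors' annotation version, the handling of reads shared by several genes, any equalising of depth between libraries and filters beyond cell calling are not stated. The matrix has 31053 genes, 27700 barcodes and 64912763 entries above 0, all whole numbers. Barcodes carry a library number, 1, 2 or 3, and neither the files nor the labels map these numbers to samples. For that reason groups were not assigned from the values or the order of the files, and no comparison between groups, gene list test between groups or shared direction of both exposures was computed. Gene positions came from GENCODE M21, in which 30934 of the 31053 gene identifiers were found, 30468 of them under the same symbol; 35 symbols occurred more than once in the matrix.

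Cells with at least 300 genes and at most 20% mitochondrial UMIs were kept. Under the gene minimum were 1015 barcodes, 993 of them in library 1, and a further 668 exceeded the mitochondrial limit. Doublets were scored per library with Scrublet as implemented in scanpy 1.11.5, with an expected rate of 6.0% and a score threshold of 0.25, which removed 971 cells (3.73%), 127 in library 1, 605 in library 2 and 239 in library 3. The filters kept 90.4% of barcodes, 75.8% in library 1, 92.6% in library 2 and 95.9% in library 3. The lowest barcode held 352 UMIs in library 1 and 500 UMIs in libraries 2 and 3. Kept cells had a median of 2892, 2899 and 1280 genes in libraries 1, 2 and 3. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes, ranked within libraries among genes in at least 10 cells, were scaled with values limited to 10, and 30 principal components and 15 neighbours were used, with shared-neighbour weights, for Leiden clustering at resolution 1.0. All libraries were clustered together without batch correction, since library and group cannot be separated. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2 and igraph 0.11.9, with random seed 0.

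Clusters were named from 29 marker lists. A marker counted as detected in at least 20% of a cluster's cells, and a name needed 3 detected markers and a mean log2 CPM of the list at least 1.0 above its median over clusters, with an offset of 20 CPM. The 10 leading genes of a cluster, among those in at least 25% of its cells, decided between classes whose scores lay within 1.0. Clusters stayed unnamed if they had fewer than 10 cells, markers of more than 1 lineage within that distance, or low depth and no marker among the leading genes. Names ending in "-like" rest on these markers alone. A class was compared at 50 cells or more, and a library's value was given at 20 cells or more. Levels are CPM of the counts summed over the cells of a class, with exact Poisson 95% intervals, and shares have exact binomial (Clopper-Pearson) 95% intervals.

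The genes named follow a rule. Each class's detected markers can be named, and for each of 32 gene lists the 3 members with the highest CPM in the class where the summed CPM of the list was highest. This gave 96 entries and 91 distinct genes, each with its range over libraries; a few gene values are not reported here. A list member counted as present at 10 CPM and 20 UMIs or more. The filters, marker lists, gene lists, this rule and most alternatives were chosen before the data were examined; the score limits of the naming rule were set afterwards. Marker lists for rod photoreceptors, microglia, Y-linked genes and pancreatic acinar enzymes, and 2 lists of glucocorticoid and fasting genes, were written later, for the tests in the closing section.

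The procedure was tested on simulated data drawn as Poisson counts at the depths of the epithelial-like and fibroblast-like sums, with known genes changed between them. Of genes changed 1.5-fold, 98.6% of 71 were recovered within 0.2 on the log2 scale, of those changed 2-fold 98.5% of 66, and of those changed 4-fold 98.4% of 63. Estimated folds were divided by the known shift of the unchanged genes, which real counts do not give. Both profiles were otherwise the same. The intervals covered 95.0% of simulated values, which were Poisson counts as the intervals assume. The simulation thus covers counting error only, not spread between cells, libraries or animals. With cluster sums redrawn and detection kept, 44 of 44 clusters kept their name or stayed unnamed as before. With genes shuffled 0 clusters took a name. Alternatives changed the gene minimum, the mitochondrial limit, doublet removal, clustering resolution, number of components, the denominator of shares, the weight of cells and libraries, the scale on which lists were summed, and the libraries and clusters included.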

Results

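Gallbladders of male C57BL/6 mice were profiled by droplet-based 3′ single-cell RNA sequencing after oral gavage with nanoplastics, plastic particles below the micrometre scale. The labels describe 3 groups: a control given vehicle for 6 weeks, mice exposed for 3 weeks and mice exposed for 6 weeks. Each group was 1 library made from 10 pooled gallbladders, so there were no replicates. The design asks how a short and a long exposure differ from the control. The deposited counts join the 3 libraries in a matrix of 31053 genes and 27700 barcodes, in which a barcode carries a library number and no sample name. No library could be assigned to a group, so exposed and control gallbladders were not compared. Values are given over all cells and for libraries 1, 2 and 3, which are unassigned and are not replicates. Total counts were 72943584 UMIs over 5643 barcodes in library 1, 121349261 UMIs over 11827 barcodes in library 2 and 58172348 UMIs over 10230 barcodes in library 3. After filtering, 25046 cells were kept, 4277 from library 1, 10956 from library 2 and 9813 from library 3, with medians of 10331, 9334.5 and 2288 UMIs per cell.

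The kept cells were mainly epithelium, fibroblasts and immune cells. Epithelial-like cells made up 37.2% of them (9312 of 25046 cells, exact binomial 95% interval 36.6 to 37.8%). Fibroblast-like cells made up 20.7% (20.2 to 21.2%), smooth muscle-like cells 6.62% (6.31 to 6.93%) and endothelial-like cells 4.85% (4.59 to 5.12%). Immune classes together made up 23.5% (22.95 to 24.0%), led by neutrophil-like cells at 6.94%, macrophage-like cells at 6.01% and T cell-like cells at 5.83%. Dendritic cell-like cells were 2.66%, mesothelial-like cells 2.24%, lymphatic endothelial-like cells 1.12%, pericyte-like cells 0.88% and innate lymphoid cell-like cells 0.85%. The remaining named classes, NK cell-like, plasma cell-like, Schwann and glia-like, tuft cell-like and mast cell-like cells, lay between 0.14 and 0.57%. With 20 principal components the innate lymphoid cell-like share was 1.84%, the plasma cell-like share 0.71% against 0.46%, and the tuft cell-like share 0.16% against 0.29%. At resolution 0.5 the tuft cell-like share was 0.52%. A further 580 cells, 2.32%, fell in 4 unnamed clusters of the 44. These intervals, and all intervals given for counts, cover counting error only.

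The makeup of the 3 libraries differed by far more than counting error. Epithelial-like cells were 34.35% of library 1 (32.9 to 35.8%), 58.3% of library 2 (57.3 to 59.2%) and 14.9% of library 3 (14.2 to 15.6%). Fibroblast-like cells were 16.8% of library 1, 9.78% of library 2 and 34.6% of library 3. Smooth muscle-like cells were 4.40%, 3.08% and 11.55% of libraries 1, 2 and 3, and endothelial-like cells 3.83%, 2.13% and 8.34%. Macrophage-like cells were highest in library 1 at 11.5%, against 3.53% in library 2 and 6.39% in library 3. Of the 492 macrophage-like cells of library 1, 136 were in cluster 34, which stood apart by microglia genes and Xist, and without clusters 34 and 36 the pooled macrophage-like share was 5.51%. T cell-like cells were highest in library 2 at 8.18%, against 5.52% in library 1 and 3.35% in library 3. Neutrophil-like cells were 9.73%, 6.57% and 6.12% of libraries 1, 2 and 3. Immune classes together were 32.1% of library 1, 24.1% of library 2 and 19.1% of library 3. Without library 2 the pooled epithelial-like share was 20.8%. Without library 3 the pooled shares were 11.75% for fibroblast-like, 3.45% for smooth muscle-like and 2.61% for endothelial-like cells. Mesothelial-like, lymphatic endothelial-like, Schwann and glia-like and mast cell-like cells came largely from library 3, without which they were 0.72%, 0.27%, 0.09% and 0.08%. Tuft cell-like cells were 0.40%, 0.11% and 0.44% of libraries 1, 2 and 3, and 0.19% without library 3. Without library 2 the mesothelial-like, lymphatic endothelial-like and Schwann and glia-like shares were 3.54%, 1.85% and 0.55%. Cells were released with trypsin from minced tissue, per the labels, and the libraries differed in depth, both of which can set such shares.

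**Figure D1:**
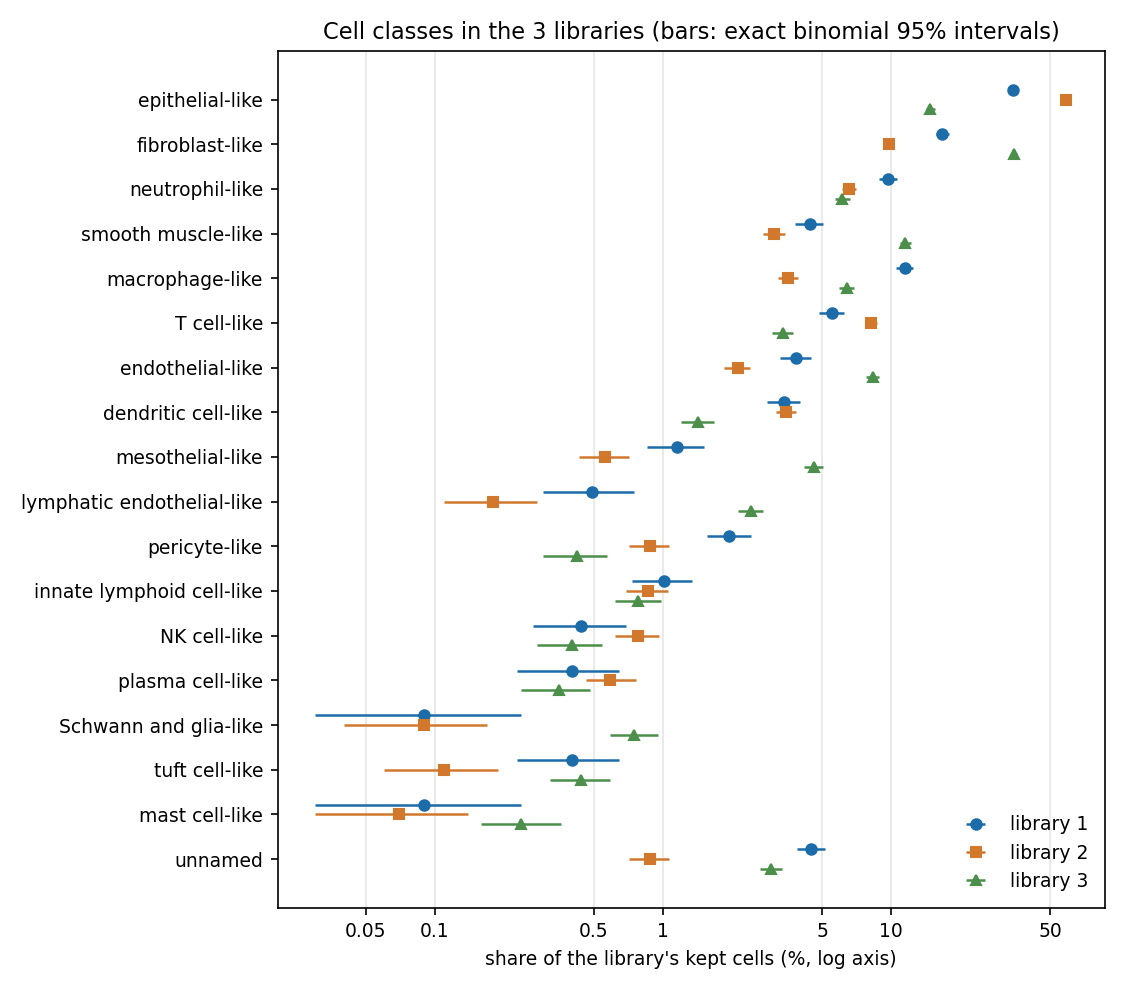
Share of each library's kept cells in each cell class, in percent on a log axis, for the 3 unassigned libraries, with bars for exact binomial 95% intervals of counting error. Library 3 had the lowest epithelial-like share, 14.9%, and the highest fibroblast-like share, 34.6%.

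The epithelium carried the genes of bile acid uptake, bicarbonate transport, mucosal protection and xenobiotic metabolism. Of the 32 gene lists, 7 were highest in epithelial-like cells by the summed CPM of their members, taken from the UMIs summed over all cells of a class. Slc10a2, the apical sodium-dependent bile acid transporter (ENSMUSG00000023073, chromosome 8, 5083219 to 5105351, GRCm38), was at 189.5 CPM (exact Poisson 95% interval 187.5 to 191.6). Its median over the other classes was 13.6 CPM, and its level in libraries 1, 2 and 3 was 184.7, 189.1 and 198.9 CPM. The other named members of the bile acid list were Slco2a1, a prostaglandin transporter, at 151.4 CPM (117.6 to 205.3 CPM over libraries) and Abcc3, an efflux pump for conjugated bile salts, at 118.7 CPM (102.7 to 131.3 CPM). Of the 14 members of that list, 8 were at 10 CPM and 20 UMIs or more in epithelial-like cells. Endothelial-like cells came close to the epithelium for this list, 582 against 645 CPM, and were highest in library 1; Slco2a1 was higher there, at 241.9 CPM.

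Among the genes of bicarbonate, chloride and water transport, 16 of 20 passed that minimum in epithelial-like cells, and their sum was 5777 CPM. The sodium pump subunit Atp1b1 was at 1439 CPM (1434 to 1445), the sodium bicarbonate cotransporter Slc4a4 at 1373 CPM (1367 to 1378) and carbonic anhydrase Car2 at 1019 CPM (1015 to 1024). Slc4a4 was at 1016 CPM in library 1, 1202 CPM in library 2 and 2507 CPM in library 3, whereas Car2 lay between 974 and 1051 CPM. Tuft cell-like cells, an epithelial class, had a similar sum of 5051 CPM and slightly more Atp1b1, 1525 CPM. The mucin and trefoil factor list was at 2887 CPM in the epithelium and 1273 CPM in tuft cell-like cells. The trefoil factors Tff2 and Tff3, which protect mucosal surfaces, were at 1122 CPM (1117 to 1127) and 389 CPM (386 to 392), and the membrane mucin Muc1 at 745 CPM (741 to 749). Tff2 ranged from 841 CPM in library 3 to 1294 CPM in library 2. Of the gel-forming mucins, chosen after their values were seen, Muc2, Muc5ac and Muc5b had 16, 13 and 5 UMIs among all epithelial-like cells. Muc6 had 1192 UMIs, in 0.7% of these cells, at 8.1, 1.6 and 22.4 CPM in libraries 1, 2 and 3, and was higher in mesothelial-like cells, at 81.9 CPM.

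Junction genes were also highest in the epithelium, at 5020 CPM against 4181 CPM in lymphatic endothelial-like cells, with Cldn7 at 854 CPM, Cdh1 at 541 CPM and Cldn3 at 528 CPM. These 3 genes were among the markers from which the class was named. Cldn3 was at 277 CPM in library 3 against 583 CPM in library 1 and 579 CPM in library 2. Xenobiotic metabolism genes summed to 3456 CPM, led by the glutathione transferase Gsto1 at 1547 CPM (1541 to 1553), the glucuronosyltransferase Ugt2b34 at 514 CPM and the sulfotransferase Sult1c2 at 377 CPM. Ugt2b34 was at 443, 457 and 815 CPM in libraries 1, 2 and 3. The metallothioneins Mt1 and Mt2, which bind copper and zinc, were at 3607 and 585 CPM in epithelial-like cells, and the copper chaperone Atox1 was at 328 CPM. Gapdh, Aldoa and Ndrg1 of the hypoxia and glycolysis list were at 638, 581 and 288 CPM. That list was nearly level between epithelial-like and pericyte-like cells, 3047 against 3016.5 CPM, and its highest class changed under 5 alternative settings. Gapdh was higher in pericyte-like cells, at 655 CPM, and Ndrg1 in lymphatic endothelial-like cells, at 691 CPM. Pericyte-like cells held the mucin list at 1675 CPM in library 2, against 64.7 and 209 CPM in libraries 1 and 3. Some of their counts may thus be epithelial RNA, and its part in their sums was not tested. The copper list was highest in epithelial-like cells in library 3 only, and the hypoxia list in libraries 1 and 3.

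**Figure D2:**
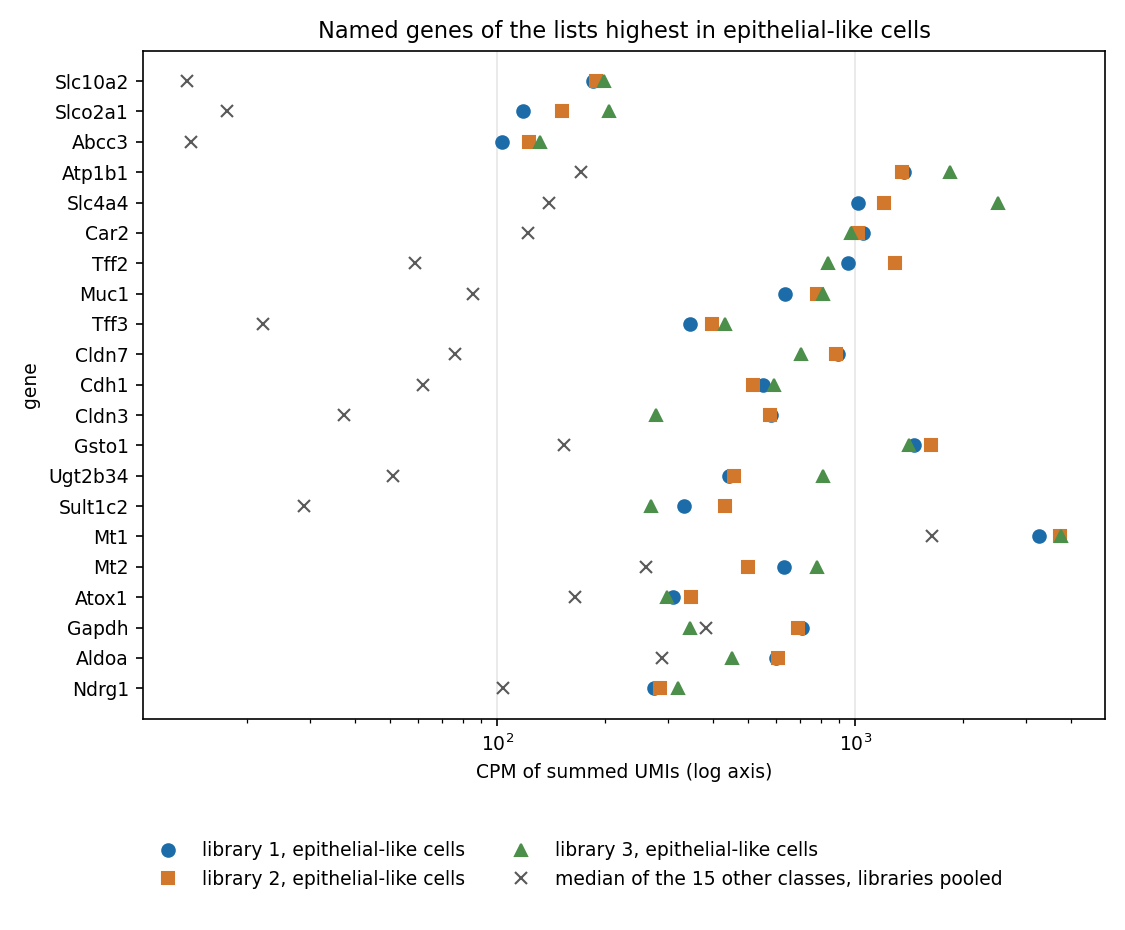
CPM, on a log axis, of the named genes of the lists that were highest in epithelial-like cells, for epithelial-like cells of each of the 3 unassigned libraries, with crosses for the median over the other classes. Slc10a2 lay between 184.7 and 198.9 CPM in the libraries, whereas Slc4a4 ranged from 1016 CPM in library 1 to 2507 CPM in library 3.

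Most epithelial-like cells of library 3 fell in other clusters than those of libraries 1 and 2. Without batch correction, clusters may split by library as well as by kind of cell, here and in the classes below. Cluster 7 held 60.8% and cluster 19 held 29.7% of the epithelial-like cells of library 3. In library 1 clusters 1, 2 and 8 held 32.3%, 45.3% and 16.1%, and in library 2 they held 41.1%, 33.8% and 9.7%. Clusters 18 and 23 held 7.6% and 6.5% of the epithelial-like cells of library 2, and 1.6% and 0.9% of those of library 1. Median depth in epithelial-like cells was 27785 UMIs in library 1, 12406 UMIs in library 2 and 13467 UMIs in library 3. Epithelial transcripts were also counted in other cells, and free RNA and remaining doublets were not told apart as their origin. Krt8, a keratin of simple epithelia, was at 162.5 CPM in the T cell-like cells of library 1, 921 CPM in library 2 and 1323 CPM in library 3. In epithelial-like cells Krt8 was at 5034, 4958 and 3318 CPM in the same libraries.

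**Figure D3:**
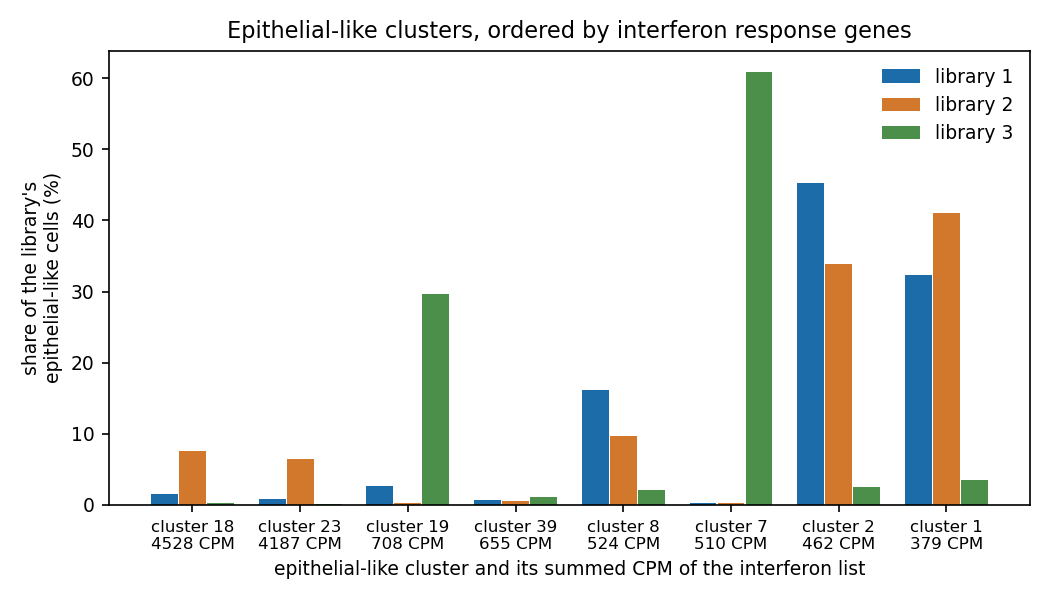
Share of each library's epithelial-like cells, in percent, in each epithelial-like cluster, ordered by the summed CPM of the interferon response list written under each cluster. Library 3 was mainly in clusters 7 and 19, at 60.8% and 29.7% of its epithelial-like cells, and clusters 18 and 23, at 4528 and 4187 CPM, came mainly from library 2.

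The stromal classes divided matrix, contractile and vascular genes between them. Extracellular matrix genes were highest in fibroblast-like cells, at 32678 CPM against 20547 CPM in smooth muscle-like cells, and in each of the 3 libraries. The collagen genes Col1a2 (ENSMUSG00000029661, chromosome 6, 4504814 to 4541544), Col1a1 and Col3a1 were at 7735 CPM (7696 to 7774), 4553 CPM and 4344 CPM. All 3 were lowest in library 3, Col3a1 at 2894 CPM against 5884 CPM in library 1 and 4908 CPM in library 2. The collagens were markers of the fibroblast class, and fibroblast-like clusters 9 and 10 held 797 and 731 cells of library 3 but at most 35 of any other library. Contractile genes reached 51129 CPM in smooth muscle-like cells and 7055 CPM in pericyte-like cells, the next class. Smooth muscle actin Acta2 was at 9913 CPM, Tagln at 9775 CPM and the myosin heavy chain Myh11 at 5680 CPM, all 3 of them naming markers. Tagln was at 12620, 14408 and 6628 CPM in libraries 1, 2 and 3. It was at 6515 CPM in smooth muscle-like cluster 13 and 10667 CPM in cluster 6. Cluster 13 held 31 of 188 smooth muscle-like cells of library 1, 46 of 337 of library 2 and 584 of 1133 of library 3.

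The list of matrix proteases and their inhibitors had its highest sum in pericyte-like cells, although only 2 of its 20 members were highest there and fibroblast-like cells led on the mean log2 scale. In pericyte-like cells the inhibitor Timp3 was at 3801 CPM (3676 to 3929), against 3878 CPM in lymphatic endothelial-like cells. The aggrecanase genes Adamts1 and Adamts4 were at 3787 CPM (3662 to 3915) and 1342 CPM (1268 to 1419). Adamts1 was at 4176, 2689 and 6757 CPM in libraries 1, 2 and 3. Endothelial-like cells were highest for vessel genes, at 12285 CPM, and for interferon response genes, at 7888 CPM against 5702 CPM in pericyte-like cells. Among vessel genes the receptor Flt1, a naming marker, was at 2692 CPM (2633 to 2752), with a library range of 2432 to 2873 CPM. The shear-responsive factor Klf2 was at 1532 CPM over all libraries and at 534 CPM without library 3. It was at 550.0 and 509 CPM in libraries 1 and 2 against 2682 CPM in library 3. Klf2 is also on the immediate early list and was highest in library 3 in each of the 7 largest classes. Klf4 was at 1297 CPM (741 to 1703 CPM over libraries). Of 30 interferon response genes, 27 passed the minimum in endothelial-like cells. The antiviral membrane protein gene Ifitm3 was at 2045 CPM, with 2776, 4008 and 644 CPM in libraries 1, 2 and 3 and 3261 CPM without library 3. The guanosine triphosphatase Iigp1 was at 1194 CPM and the transcription factor Irf1 at 574 CPM. The senescence list had its highest pooled sum in mesothelial-like cells, but 84.5% of it was Igfbp5, at 8792 CPM. That call held in library 3 only, and without library 3 endothelial-like cells were higher, at 8224 against 5860.1 CPM. Endothelial-like cells also led with each library weighing the same, and fibroblast-like cells on the mean log2 scale. Igfbp7 was at 507 CPM and Igfbp4 at 457 CPM. Igfbp5 was at 11046 CPM in library 3 against 4792 CPM in library 1 and 3429 CPM in library 2. Without library 3, Igfbp5 and Igfbp4 were at 4287 and 204.5 CPM.

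Neutrophil-like cells had the highest pooled sum for 7 lists, which covered inflammatory cytokines, chemokines, inflammasome, apoptosis, granule, iron and oxidative stress genes. These lists share genes and are not separate results. Il1b made up 79.3% of the inflammasome sum and 51.1% of the cytokine sum. Fth1 made up 69.2% of the iron sum and 64.8% of the oxidative stress sum. Members highest in this class ranged from 3 of 27 for chemokines to 17 of 21 for granule genes. Il1b, the gene of interleukin 1 beta (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139), was at 10991 CPM (10855 to 11128). It was at 11798, 9151 and 12263 CPM in libraries 1, 2 and 3, and the next class, dendritic cell-like cells, was at 1993 CPM. The inhibitor Nfkbia was at 2967 CPM, the inflammasome sensor Nlrp3 at 1118 CPM and Txnip at 1479.6 CPM. Tnfaip2 was at 1660.1 CPM, with 1197, 936 and 3448 CPM in libraries 1, 2 and 3 and 1077 CPM without library 3. The chemokine gene Cxcl2 was at 13187 CPM, with 19258 CPM in library 1, 11289 CPM in library 2 and 5862 CPM in library 3, and made up 83.0% of its list. Macrophage-like cells were close for that list, at 15047 against 15887 CPM, and were the highest class in library 2, without library 1, at 10% mitochondrial UMIs and on the mean log2 scale. Ccl3 and Ccl4 were at 1013 and 875 CPM. The survival factor Mcl1 was at 3061 CPM, with Gadd45b at 1485 CPM and Cdkn1a at 613 CPM. The granule list was at 27528 CPM against 2164 CPM in epithelial-like cells, the next class. The calprotectin genes S100a9 and S100a8 were at 9325 and 8438 CPM, and the decoy receptor Il1r2 at 2283 CPM. All 3 are naming markers of the class. S100a9 was at 11101 CPM in library 1, 12752 CPM in library 2 and 1551 CPM in library 3, where cluster 14 held 580 of 601 neutrophil-like cells. Cluster 5 held 411 of 416 such cells in library 1 and 719 of 720 in library 2.

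The ferritin genes Fth1 and Ftl1 led both the oxidative stress and the iron lists in neutrophil-like cells, at 17714 and 3278 CPM. Slc7a11, the cystine transporter, was at 1488 CPM (1438 to 1539), against 199.8 CPM in dendritic cell-like cells, the next class. Fth1 was at 16691 CPM in library 1, 27969 CPM in library 2 and 4896 CPM in library 3. Macrophage-like cells were close to neutrophil-like cells for both lists, at 25213 against 27324 CPM and 23809 against 25611 CPM, and were the highest class in library 1, without library 2 and at 10% mitochondrial UMIs. For the oxidative stress list tuft cell-like cells led in library 3, at 13456 against 10865 CPM, and on the mean log2 scale, so neutrophil-like cells were highest in library 2 only.

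Macrophage-like cells were highest for lipid transport, complement and lysosome genes in each of the 3 libraries. Apoe, the apolipoprotein E gene (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188), was at 18772 CPM (18662 to 18883) and made up 87.1% of the lipid list. Apoe was at 20039, 30326 and 4552 CPM in libraries 1, 2 and 3. Fibroblast-like cells had the same order of libraries, at 2194, 4499 and 1075 CPM, as did smooth muscle-like and endothelial-like cells. In epithelial-like, neutrophil-like and T cell-like cells Apoe was highest in library 3. Among macrophage-like cells Apoe was at 21327 and 35723 CPM in clusters 26 and 27, which held few cells of library 3. The sterol carrier Npc2 was at 862 CPM and the cholesterol exporter Abca1 at 390.1 CPM. The complement genes C1qa, C1qb and C1qc were at 2936, 2327 and 1759 CPM, and no other class exceeded 37.2 CPM of C1qb. With Apoe they were naming markers. C1qb was at 540 CPM in library 3 against 2798 CPM in library 1 and 3182 CPM in library 2. The class was made up of different clusters by library, which clustering without batch correction can bring about by itself. Cluster 15 held 458 of 627 macrophage-like cells of library 3. Clusters 26 and 27, with C1qb and Apoe among their leading genes, held 7 and 8 of them. Those 2 clusters held 137 and 100 cells of library 1, and 131 and 160 cells of library 2. The protease Ctsb was at 2310 CPM and the adaptor Tyrobp at 1378 CPM, below its 3541 CPM in neutrophil-like cells. Dendritic cell-like cells were highest for MHC class II genes, at 48335 CPM against 42413 CPM in macrophage-like cells. Cd74 was at 19037 CPM, H2-Aa at 9230 CPM and H2-Ab1 at 9173 CPM, and each was lowest in library 3, Cd74 at 11195 CPM. The dendritic cell-like clusters also differed by library. Cluster 24, with Cd74 at 22919 CPM, held 78, 298 and 8 cells of libraries 1, 2 and 3. Cluster 29, with Cd74 at 14019 CPM, held 57, 73 and 107.

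Lymphoid cells held cytotoxic, type 2 and immunoglobulin transcripts. In NK cell-like cells, 143 in all, the chemokine gene Ccl5 was at 3652 CPM (3444 to 3869), the granzyme gene Gzma at 1122 CPM and Nkg7 at 773 CPM. Their next class was T cell-like cells, at 1141, 87.4 and 193.6 CPM. Gzma and Nkg7 were naming markers of the class. The summed MHC class I list was also highest there, with 6 of its 14 members highest in this class. H2-K1 was at 3141 CPM and H2-D1 at 1991 CPM, and B2m, at 2437.5 CPM, was level with macrophage-like cells at 2441 CPM. The markers detected in innate lymphoid cell-like cells included Gata3 at 1239 CPM, Il5 at 699.5 CPM, Il13 at 248 CPM and the interleukin 33 receptor gene Il1rl1 at 676 CPM, which describe the cluster and are no separate result. Plasma cell-like cells, 116 in all, had 464868 CPM of immunoglobulin list genes, with Igkc at 306751 CPM, Igha at 107679 CPM and Jchain at 46527 CPM, Igha and Jchain being naming markers. At resolution 2.0 the class divided into 90 plasma cell-like and 26 B cell-like cells, so it holds cells with B cell markers. Ighg1 had 17 UMIs in them. The secretory chaperone Hsp90b1 and the factor Xbp1 were at 1698 and 1411 CPM, and Hspa5 at 869 CPM, below the median of 901.5 CPM over the other classes and the 2157 CPM in pericyte-like cells. The endoplasmic reticulum stress list, highest in plasma cell-like cells when pooled, was highest in fibroblast-like cells in library 2 and in pericyte-like cells without library 3. Each library weighing the same, Hsp90b1 and Xbp1 were at 2811 and 2292 CPM.

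Lists highest in the smallest classes rest on few cells. Tuft cell-like cells, 72 in all, were highest for cholesterol synthesis, with Hmgcs1 at 318 CPM (284 to 355) and Idi1 at 168 CPM. Schwann and glia-like cells had nearly the same sum for that list, 1998 against 2005 CPM, and epithelial-like cells had 1792 CPM. For the nuclear genes of the respiratory chain, tuft cell-like cells were at 14624 CPM and epithelial-like cells at 14276 CPM, with Cox8a, Cox6c and Uqcrh at 2146, 1663 and 1586 CPM in the former. Schwann and glia-like cells, 88 in all and 74 of them in library 3, had the highest pooled sums for cell cycle and for immediate early genes. The cell cycle call did not hold in library 3, the only library with a value for this class, where dendritic cell-like cells were at 4623 against 1904 CPM. It also changed with each cell or each library weighing the same, at 10% mitochondrial UMIs, on the mean log2 scale and without libraries 2 or 3, and only 4 of its 23 members passed the minimum. The Tubb5, Stmn1 and Hmgb2 were at 719, 699 and 395 CPM in Schwann and glia-like cells, with Tubb5 and Stmn1 at 389.6 and 451 CPM without library 2. Egr1, Fos and Junb were at 8373, 8353 and 6145 CPM in Schwann and glia-like cells. Fibroblast-like cells followed for the immediate early list with 54107 against 62484 CPM, and were the highest class without library 3. These genes respond to tissue dissociation as well as to stimuli in the animal.

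**Figure D4:**
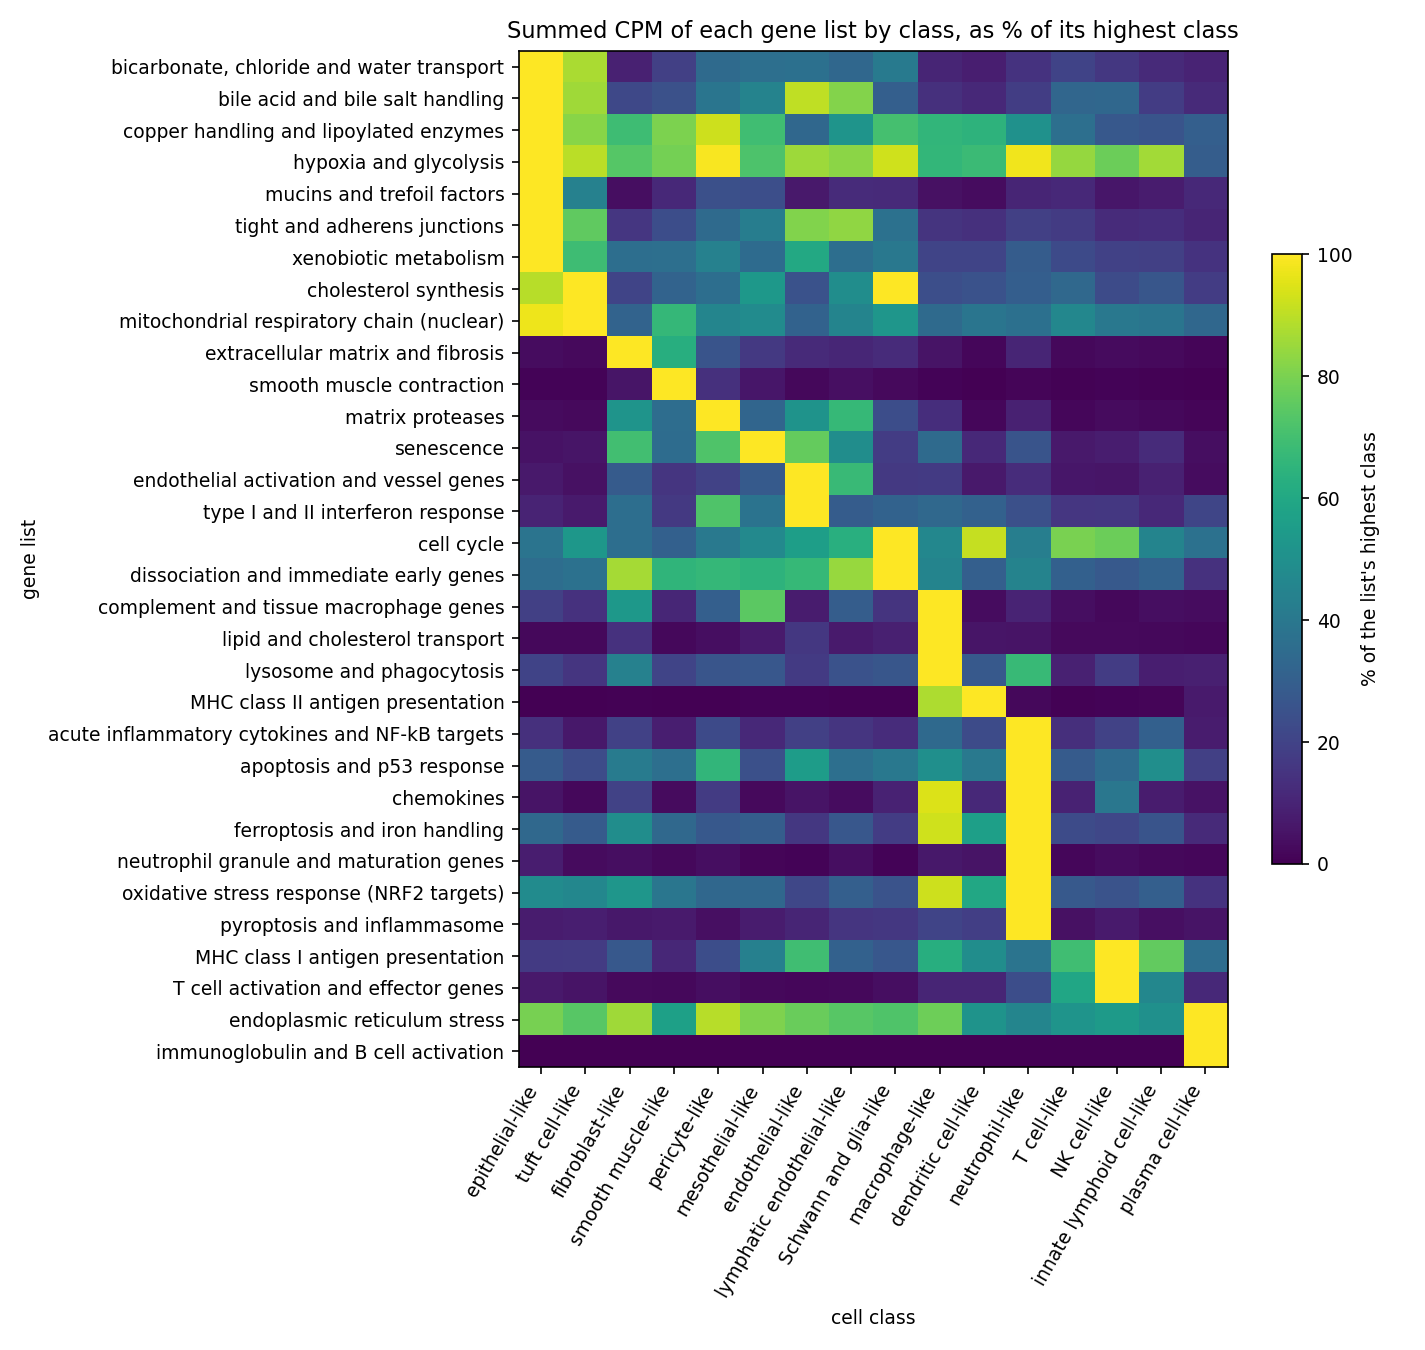
Summed CPM of each of the 32 gene lists (vertical axis) in each of the 16 classes with at least 50 cells (horizontal axis), as a percent of the list's highest class, over all libraries. Neutrophil-like and epithelial-like cells were each the highest class for 7 lists, and lists such as hypoxia and glycolysis and endoplasmic reticulum stress were spread over many classes.

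The class in which a list was highest was the same in every library with a value for 23 of the 32 lists. For 3 of these, the cholesterol synthesis, respiratory chain and immediate early lists, only library 3 had a value in that class, so libraries could not be compared. The highest class stayed the same under every alternative setting in which lists were summed for 19 lists, which included the bile acid, bicarbonate, mucin, junction, xenobiotic, matrix, contractile, vessel, interferon, lipid, complement, lysosome, granule and inflammatory cytokine lists. It changed under at least 1 setting for the other 13: the copper, hypoxia, cholesterol synthesis, respiratory chain, oxidative stress, iron, chemokine, matrix protease, cell cycle, senescence, T cell activation, endoplasmic reticulum stress and immediate early lists. Beyond those already given, named genes higher in another class than that of their list were Mt2, Atox1, Ftl1, Cdkn1a, Txnip, Ccl4, Klf2, Klf4, Igfbp4, Igfbp7, Hmgb2, Idi1 and Cox8a. Genes with near-identical copies or many pseudogenes, such as H2-K1, H2-D1, Fth1, Ftl1, Gapdh, Tubb5, Igkc and Igha, are uncertain, since how shared reads were counted is not stated.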

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

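All tests in this part were chosen after the result was seen. Signals stood out in data outside the named classes and the kept cells. Unnamed cluster 36, 96 cells all from library 1, held 2797 UMIs of 10 rod photoreceptor genes, with Sag at 11027 CPM and Gngt1 at 7184 CPM among them. Other kept cells of library 1 had 6.9 CPM of these genes. The cluster also held 67 UMIs of Xist, the transcript of the inactive X chromosome, and 0 Y-linked UMIs, although the labels give males only. Among the 993 barcodes of library 1 under the gene minimum, haemoglobin genes were at 6395 CPM, against 0.5 CPM in its kept cells and 4.4 CPM as the level that 3 counts give. The same barcodes held 166 rod UMIs, and Gm42418, a gene overlapping ribosomal RNA repeats, took 15.9% of their UMIs against 3.43% in kept cells. The haemoglobin and Gm42418 values were not weighed further.

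Cluster 34, a macrophage-like cluster of 140 cells with 136 from library 1, went with cluster 36. It had 5156 CPM of 8 microglia genes, with Cx3cr1 at 1067 CPM and Olfml3 at 607 CPM among them, against 865.5 CPM in the other macrophage-like cells of library 1, with all but Sall1 of them detected there. It had 73 Xist UMIs and 1 Y-linked UMI. Free RNA spread evenly over library 1 is argued against, since cluster 36 held 84.6% of its 3306 rod UMIs with 0.082% of its UMIs. That cluster was picked for its rod genes, and rod RNA was not confined to it. Rod genes were at 494 CPM in cluster 34 and 244 CPM in the left-out barcodes under the gene minimum. Median depth was 469 UMIs in cluster 36 and 465 UMIs in those barcodes. A library 1 taken wholly from animals outside the labels' sex is argued against too. Its other cells had Y-linked genes at 199.4 CPM, 1.13 times the lower of libraries 2 and 3. Other male animals cannot be told apart by these genes. The level in other macrophage-like cells gives 23.4 Y-linked UMIs in cluster 34 (95% interval 14 to 33), so the values are consistent with cells from an animal outside the labels' sex. Rod photoreceptors and microglia of the retina are a candidate source, and how such cells entered the library was not tested. No biological explanation was tested, as the group of library 1 is unknown.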

How the results depend on the processing

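The alternatives that left out a library or clusters 34 and 36, and the mean log2 scale for lists, were chosen after the data were seen. The order of the largest shares, epithelial-like above fibroblast-like, held under each setting except without library 2. The epithelial-like share, 37.18% as reported, was 40.53% with at least 500 genes, 39.67% with no mitochondrial filter, 38.08% with no doublet removal, 38.8% at resolution 0.5, 38.6% at resolution 2.0, 38.64% with 20 principal components, 20.79% without library 2, 51.55% without library 3 and 50.1% of non-immune cells. The fibroblast-like share, 20.69%, was 21.76% with at most 10% mitochondrial UMIs, 20.08% with no doublet removal, 19.69% with 20 components, 21.49%, 29.16% and 11.75% without libraries 1, 2 and 3, and 27.87% of non-immune cells. The smooth muscle-like share, 6.62%, was 5.46% with at most 10% mitochondrial UMIs, 7.08%, 9.38% and 3.45% without libraries 1, 2 and 3, and 8.92% of non-immune cells. The endothelial-like share, 4.85%, was 6.97% and 2.61% without libraries 2 and 3, and 6.54% of non-immune cells. The immune share, 23.47%, was 21.86% with at least 500 genes, 24.4% with at most 10% mitochondrial UMIs, 22.12% with no doublet removal, 22.83% at resolution 2.0, and 21.7% and 26.31% without libraries 1 and 3. The cause was not tested, other than that a changed denominator or fewer libraries follows from the setting itself. With at least 200 genes all 18 shares stayed inside their intervals. NK cells were not named with no mitochondrial filter, at resolution 0.5 or with 20 components, mast cells not at resolution 0.5 or with 20 components, and tuft cells not at 10% mitochondrial UMIs. With 20 components innate lymphoid cells were 1.84%, plasma cells 0.71% and tuft cells 0.16%, and at resolution 0.5 tuft cells were 0.52%. Without clusters 34 and 36 the macrophage share, 6.01%, was 5.51%, the 1 of 18 shares that moved. Of 32 lists, the highest class was as reported for 29 with each cell weighing the same, 30 with each library weighing the same, 31 with no doublet removal, 25 at 10% mitochondrial UMIs, 23 on the mean log2 scale, 28, 29 and 24 without libraries 1, 2 and 3, and 32 without clusters 34 and 36. Named genes lay within 1.5 times their value for 91 of 96 entries with each cell weighing the same, 93 of 96 with each library weighing the same, 94 of 96 without library 2, 79 of 84 without library 3, and all entries with a value under the other settings that sum counts. With each cell weighing the same, Tubb5 was 329, Stmn1 375, Hmgb2 622, Igfbp4 867 and Uqcrh 1049 CPM. No paired analysis was possible because each group is a pool and barcodes do not name samples. For the latter reason the alternatives for comparisons of groups (TMM factors, other totals, other minimums, thinning of cells, a split control) were not run. Depth limits low-level genes in the classes with few cells, and was a median of 10331, 9334.5 and 2288 UMIs per cell in libraries 1, 2 and 3, whose mix of classes differed.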

Other observations

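In this part, the tests of depth, of a shift shared by other classes and of Ctrb1 were chosen after the result was seen, and the tests of free RNA in library 3 and of glucocorticoid and fasting genes before it. The genes named here were chosen after their values were seen. Epithelial-like clusters were sorted into 2 kinds, by whether the water channel gene Aqp1 or the iron-binding defence gene Lcn2 was higher. The split was not clean. Cluster 8 had Lcn2 at 500 CPM, against 4493 CPM in cluster 2, and Aqp1 at 183 CPM. Cluster 39 had Lcn2 at 1574 CPM and Aqp1 at 354 CPM. The values of a kind pool its clusters. The Aqp1 kind, clusters 1, 7 and 23 with 4489 cells, was 33.6%, 47.9% and 64.4% of the epithelial-like cells of libraries 1, 2 and 3. The Lcn2 kind, clusters 2, 8, 18, 19 and 39, had 4823 cells. The sodium-proton exchanger gene Slc9a3 was at 193.1, 95.8 and 166.3 CPM in the Aqp1 kind of libraries 1, 2 and 3. In the Lcn2 kind it was at most 12.9 CPM in any library, but at 26.8 CPM in cluster 8 and 37.7 CPM in cluster 39. In the Lcn2 kind the lactoferrin gene Ltf was at 887, 1061 and 875 CPM, against at most 20.3 CPM in the Aqp1 kind, and the antimicrobial lectin gene Reg3g was at 207.4, 135.1 and 146.7 CPM, against at most 7.7 CPM. Interferon response genes were highest in clusters 18 and 23, which were 2.52% (1.78 to 3.46%) of the epithelial-like cells of library 1, 14.1% (13.25 to 14.98%) of library 2 and 0.41% (0.15 to 0.89%) of library 3. The interferon list in all epithelial-like cells was at 518, 1003 and 554 CPM, and without these clusters at 469.5, 423 and 549.8 CPM.

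Among other classes, Cyp1a1, a target of the aryl hydrocarbon receptor, was at 898, 1006 and 1493 CPM in endothelial-like cells of libraries 1, 2 and 3. It did not exceed 11.4 CPM in the other 6 of the 7 largest classes. Tiparp, on the same xenobiotic list, went the other way in endothelial-like cells, at 444, 328 and 141 CPM. T cell-like cells held the interleukin 17 gene Il17a at 375, 497 and 615.5 CPM and Il17f at 80.0, 67.6 and 69.6 CPM.

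Library 3 stood apart in epithelium, and further apart in the other 6 of the 7 largest classes. In epithelium, of 3063 genes at 50 CPM or more, 3 were 2-fold apart between libraries 1 and 2, 168 between 1 and 3, and 156 between 2 and 3. Of these genes, 49 were higher and 56 lower in library 3 than in both. In the other 6 classes, genes 2-fold apart between libraries 1 and 3 ranged from 270 in smooth muscle-like to 668 in neutrophil-like cells. Between libraries 1 and 2 they were 11 and 44 in these 2 classes. For epithelium, depth is argued against. Between libraries 3 and 2, of similar epithelial depth, 52.0 times as many genes were apart as between 2 and 1. A shift of the whole library was consistent with 85.2% of gene and class pairs (144 of 169) going the same way in 6 other classes, where chance gives 50%. Only pairs with a level in the other class at or above the epithelial level were counted. A gene could count in several classes, so the pairs are not independent. Free RNA from such classes could also carry these genes into epithelium, so the value does not tell a shift from free RNA. Nor does it say what would have shifted the library. Free RNA and a glucocorticoid or fasting response stayed open.

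Of the genes higher in library 3 epithelium, 38.8% (19 of 49) were higher over its other cells, between the levels set for and against free RNA. Over 62 epithelial-specific genes the median log2 ratio was -0.68 (bootstrap 95% interval -0.80 to -0.49), around the limit of -0.69 set at 0.5 of the median of the lower genes. The point value alone would have argued against free RNA; the interval was required only after that value was seen, and it leaves the explanation open. Lists of glucocorticoid and fasting genes reached the 95th percentile of random lists in 6 of 14 class tests. This was 5 of 7 for glucocorticoid targets and 1 of 7 for fasting genes. The limits applied to both lists jointly: at least 5 of 7 classes reaching it, or at least 5 of 7 below it. Neither held for both, which leaves the joint explanation open. Taken singly, which the rule did not foresee, the glucocorticoid list met the limit for and the fasting list the limit against. In epithelium itself the fasting list was the higher, with 11 of 12 members higher in library 3, a median log2 ratio of 0.64 and a level at the top of the random lists, against 6 of 9, 0.37 and the 95.4th percentile for glucocorticoid targets. The exposure group of library 3 is unknown and stays an untested explanation, as does a difference in handling. The immediate early list, which responds to dissociation, was at 21646, 16294 and 55003 CPM in neutrophil-like cells of libraries 1, 2 and 3, at 22069, 19286 and 49021 CPM in macrophage-like cells and at 47258, 43701 and 64629 CPM in fibroblast-like cells. In epithelium it was not highest in library 3 for the Aqp1 kind, at 33158, 27043 and 27916 CPM, and was for the Lcn2 kind, at 16046, 14593 and 25498 CPM.

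Ctrb1, a chymotrypsinogen gene of the exocrine pancreas, was at 869, 1021 and 824 CPM in epithelial-like cells of libraries 1, 2 and 3. Pancreatic cells or their RNA are argued against, since the other 7 acinar enzymes together reached at most 7.2% of Ctrb1, nearly all of it Cela1. Free RNA as the only source is argued against, since Ctrb1 was at least 12.7 times higher in the Aqp1 kind than in the Lcn2 kind in each library. Ctrb1 was itself a leading gene of clusters 1, 7 and 23, so the kinds were not independent of it. Single clusters lay closer, with 1211.5 CPM in cluster 7 against 331 CPM in cluster 8 and 534 CPM in cluster 39. T cell-like cells had 13.1, 233.8 and 511 CPM, so some counts lay outside the epithelium, from a source that was not traced. Expression by the epithelium may explain the values, but reads shared with related genes could not be tested from counts, and no biological explanation was tested.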
